A study of Bubalus bubalis with 6 samples.

How the data were processed

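Sperm DNA of 6 buffalo (Bubalus bubalis) bulls was measured on 6 arrays, 1 per bull, on 2 slides, with 3 high-fertile bulls (2, 3 and 5) and 3 subfertile bulls (1, 4 and 5), as the sample names give them. Per the labels' protocols, DNA from frozen semen was sonicated, methylated fragments were pulled down with an antibody against 5-methylcytosine and magnetic beads, and the immunoprecipitated (IP) DNA was labelled with Cy5 and the input DNA with Cy3. No dyes were swapped, so a dye effect on a probe is shared by all arrays. The arrays held 177440 probes of 60 bases and 3440 control spots. A name was given to 19762 probes, with 7932 different names, of which 6454 were found in a RefSeq gene table of the buffalo assembly NDDB_SH_1, used here for names only. A spreadsheet had turned 14 names into calendar dates, and these were not renamed. The genome build of the probe coordinates is not given in the sources used here, and coordinates are printed as the files give them, counted from 1. The files name no promoter, exon, intron or CpG island class for a probe, so no feature can be stated for a region and the planned comparison of feature classes was not run.

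The deposited scanner tables hold spot intensities on a linear scale: per the file headers they were extracted with Agilent Feature Extraction 10.7.3.1, with spatial and multiplicative detrending and a linear dye normalization. The header of subfertile bull 1 names the CGH protocol of that software and those of the other 5 arrays the ChIP protocol. Spots too dim to measure carry a substitute signal, used in at least 1 channel for 4.97% (subfertile bull 1) to 26.3% (high-fertile bull 2) of probes, which sets a floor under their signal. The deposited log10 ratio of each spot is red over green, that is IP over input, and is listed at 0 where both channels are substitutes. Other spots are listed at 0 as well: in high-fertile bull 2 it was 0 at 31882 probes, of which 13133 had substitutes in both channels. The deposited series table holds the same ratio on the log2 scale, which a comparison with the scanner files showed for all probes but 1 that the table lacks. Its column medians were 0, -0.01 and -0.04 for high-fertile bulls 2, 3 and 5 and -0.02, 0 and -0.04 for subfertile bulls 1, 4 and 5, so it was not centred; its scale and direction follow from that match.

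For each array, log2(IP/input) was computed from the processed signals and centred on the array's median over all non-control probes, without loess or quantile steps, since most probes can carry signal. Each non-control spot was kept as its own probe, and spots of the same sequence were not averaged. Probes were tested where the input signal was well above background on all 6 arrays with no non-uniformity flag, which left 110686 probes, 7644 of them named. A gene region is the mean over at least 3 tested probes with the same gene name, whatever their place in the gene, and 737 genes qualified (2779 without the filter). Runs of at least 3 probes with gaps of at most 500 bp (9463 runs, 2549 with a named probe) were added after the data were seen, because most probes have no name. Probes in dense tiles overlap and gene regions rest on few probes. A log2(IP/input) ranks regions by antibody-bound DNA and is not a share of methylated cytosines, and it also moves with the number of CpGs in a fragment. Duplicate spots of 1 sequence (1093 pairs) correlated at 0.43, 0.75 and 0.84 in high-fertile bulls 2, 3 and 5 and at 0.89, 0.53 and 0.88 in subfertile bulls 1, 4 and 5, across probes.

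High-fertile and subfertile bulls were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05), with the group as the only term. Version 1.17.8 of data.table was used to read the files, and plots were drawn with matplotlib 3.10.9. The labels do not say how the bulls were chosen, and n is the number of bulls. Scan dates in the headers put high-fertile bulls 2 and 3 and subfertile bull 4 in a first session and high-fertile bull 5 and subfertile bulls 1 and 5 on later dates. Probes, gene regions and the testable list were therefore also compared with the session as a block and within each session; runs and the unfiltered lists were fitted with the block only, and these fits were chosen after the data were seen. Of the gene regions called in these fits, 1 is not reported here by name. Within a session 1 group has a single bull, whose spread is assumed to equal that of the others.

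Design, tests, alternatives, gene lists and the naming rule were fixed before the data were examined. The rule names up to 10 gene regions and 5 probes per direction among those whose 3 bulls of a group all lie beyond the 3 of the other, first those past the threshold by size and then by unadjusted p. For each gene list it names up to 4 members by unadjusted p and, for enrichment, the 2 highest and 2 lowest. The 16 lists were genes with a maternal or a paternal imprinting mark, germline genes with methylated promoters, sperm chromatin, sperm structure and function, bull fertility proteins, capacitation signalling, developmental regulators, pluripotency, epigenetic enzymes, housekeeping genes, leukocyte and epithelial markers (other cells that semen can hold), oxidative and heat stress, reproductive hormones, and olfactory receptors. A list needed 5 measured genes. Lists were tested with limma's camera (preset correlation 0.01), and beside it with an estimated correlation and with fry. A list's enrichment within sperm was its median minus that of all gene regions per array, tested by exact sign-flip permutation over 6 arrays, where no p can be below 0.0312. The array-wide spread was tested by exact permutation of 3 against 3, where no p can be below 0.1.

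The fits of probes, gene regions and runs, with and without the session block, were tested on simulated data with the real spread. The fits within a session and the test of group by session were not simulated, so their rate of false calls is unknown. With 100 of 110686 probes changed by 1 log2 unit and 100 by 2, the probe fit called 0 of either, so it recovered no change of these sizes at this number of arrays. Among 737 simulated gene regions, limma called 73 of 100 at 1 log2 unit and 93 of 100 at 2, with 15 false calls among 181. With a session block it called 79 and 100, with 3 false calls among 182. Of these 737 regions 200 were changed, a far larger share than among probes or runs, which eases the adjusted threshold. The rates therefore do not give the power for a few changed regions. Without the block, the simulated noise did not follow sessions as the real arrays do. Among 9463 runs limma called 23 and 81 of 100, and with a session block 62 and 94. For a simulated list of 41 genes, camera called 0 of 100 lists without a shift and 100 of 100 with a shift of 0.3, and the sign-flip test 5 and 100; genes of a simulated list were independent.

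The alternatives were normexp background correction (offset 50), loess within arrays, the series table, no filter or a filter on both channels (59797 probes), quantile or scale normalization between arrays, slide as a block, the larger slide alone, removal of a trend on probe GC content, each array left out, eBayes with trend and robust, array weights, an adjusted p threshold of 0.1, the median over probes, at least 5 probes per gene, camera with an estimated correlation and the mean over a list's genes. Added after the data were seen were the session fits, scan date as a block, centring over tested probes, runs, and no filter together with the session block.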

Results

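The series asked how sperm DNA methylation differs between high-fertile and subfertile water buffalo bulls. Methylated DNA was immunoprecipitated (meDIP) from the semen of 3 high-fertile and 3 subfertile bulls and hybridised with the same bull's input DNA on an array for buffalo CpG islands and promoters. A higher log2(IP/input) marks a region with more DNA bound by the 5-methylcytosine antibody, relative to the array's median. Input DNA was well above background at 69.0% (subfertile bull 4) to 95.5% (high-fertile bull 5) of the 177440 probes. Immunoprecipitated DNA was well above background at 37.6%, 58.6% and 78.8% in high-fertile bulls 2, 3 and 5 and at 85.2%, 47.3% and 76.5% in subfertile bulls 1, 4 and 5. The number of arrays limits the precision of every comparison.

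The arrays parted by scan session. The 3 bulls scanned on the first date (high-fertile 2 and 3, subfertile 4) and the 3 scanned on later dates (high-fertile 5, subfertile 1 and 5) correlated across gene regions at 0.44 to 0.86 within a session and at -0.11 to 0.24 between sessions; genes are not independent replicates. Between sessions, with the fertility group as a second term, limma called 153 of 737 gene regions (103 higher on the later dates, 50 lower, smallest adjusted p = 0.000959) and 8941 of 110686 probes (7194 higher, 1747 lower). Arrays were centred over all probes, and the tested probes then had medians of -0.33, -0.26 and -0.26 in high-fertile bulls 2 and 3 and subfertile bull 4. In high-fertile bull 5 and subfertile bulls 1 and 5 these medians were -0.01, -0.02 and -0.10. This offset raises tested probes and genes on the later dates, so the split into higher and lower depends on the centring. Each session holds bulls of both groups, so probes, gene regions and the developmental regulators were also compared with the session as a block and within each session. Probe runs and the lists without the filter were compared with the block alone, and the spread of the arrays within sessions alone. Neighbouring probes at most 10 bp apart correlated at 0.36 (high-fertile bull 2) to 0.84 (subfertile bull 5) within an array.

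**Figure D1:**
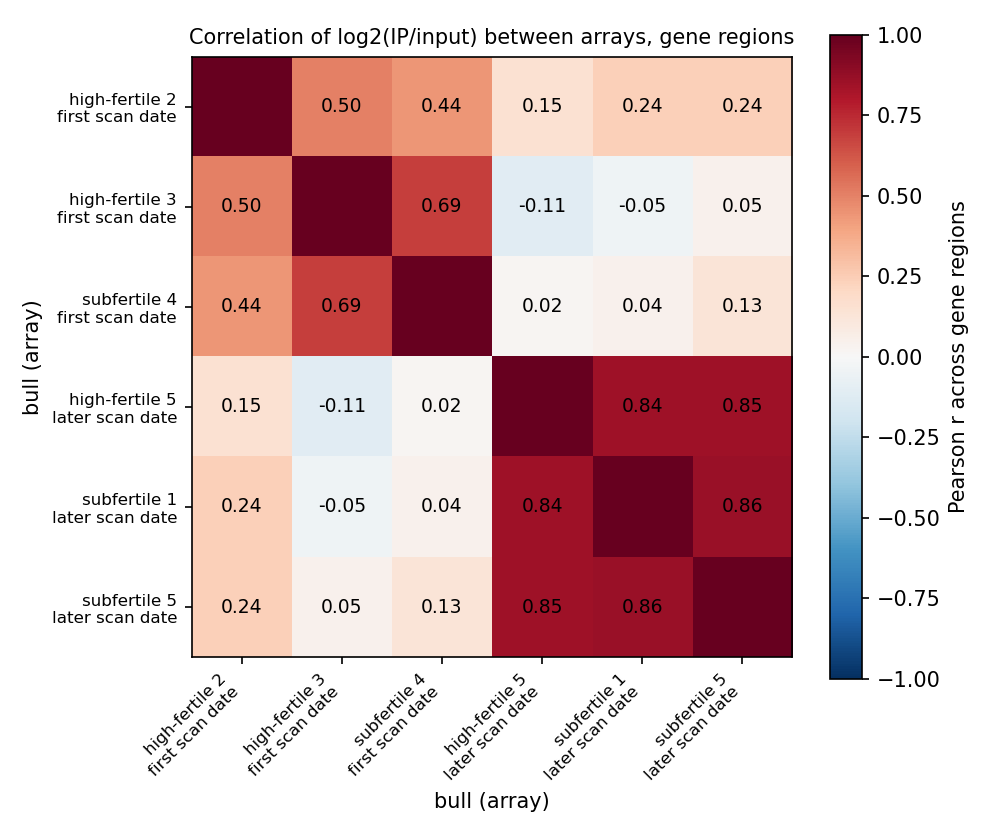
Pearson correlation of log2(IP/input) across gene regions between each pair of the 6 arrays, ordered by scan session (colour and printed value, no unit). Pairs from the same session range from 0.44 to 0.86 and pairs from different sessions from -0.11 to 0.24.

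**Figure D2:**
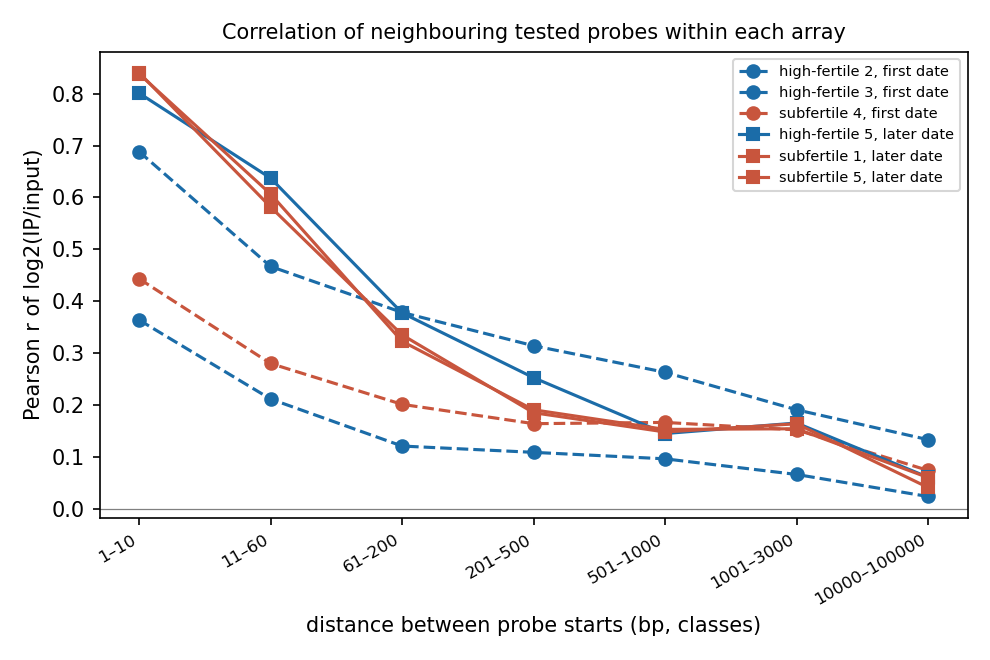
Pearson correlation of log2(IP/input) between neighbouring tested probes within each array (y axis, no unit) by distance class between probe starts (x axis, bp); circles and dashed lines are arrays of the first scan date, squares and solid lines those of later dates, blue high-fertile and red subfertile bulls. At 1 to 10 bp the correlation ranges from 0.36 to 0.84, and it is lower for distant probes on every array.

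In high-fertile compared with subfertile bulls, the gene regions with the smallest unadjusted p among those whose groups did not overlap were, on the lower side, ABCF2, an ATP-binding protein of the ABC family (-0.63 log2, SE 0.23), EIF3B, a subunit of a translation initiation factor (-0.58, SE 0.21), and SHKBP1, an adaptor-binding protein (-0.49, SE 0.21). On the higher side they were LHX4, a LIM-homeodomain transcription factor of pituitary development (0.49, SE 0.25), OPCML, a cell adhesion protein (0.37, SE 0.22), and LPXN, a focal adhesion protein (0.36, SE 0.22). All 3 bulls of a group lay beyond all 3 of the other for each of these genes, which the naming rule requires, and none of the differences passed the test.

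The ABCF2 region (5 probes, chromosome 4, 118068106 to 118082832) had a mean log2(IP/input) of -0.91 in high-fertile and -0.28 in subfertile bulls. EIF3B (3 probes, chromosome 25, 42775853 to 42776442) averaged -1.31 and -0.73, and SHKBP1 (3 probes, chromosome 18, 49528617 to 49528861) averaged -0.57 and -0.08. LHX4 (3 probes, chromosome 16, 59046874 to 59051053) averaged -0.08 in high-fertile and -0.57 in subfertile bulls. With the session as a block the differences were -0.55 for ABCF2, -0.50 for EIF3B, -0.47 for SHKBP1 and 0.39 for LHX4. On the first date and the later dates they were -0.29 and -0.80 for ABCF2, -0.60 and -0.40 for EIF3B, -0.72 and -0.22 for SHKBP1, and 0.60 and 0.18 for LHX4. Immunoprecipitated DNA was well above background at 10 of 15 high-fertile and 13 of 15 subfertile spots of ABCF2, at 5 of 9 and 8 of 9 of EIF3B, and at 5 of 9 and 7 of 9 of OPCML. It was so at 7 of 9 and 8 of 9 spots of both SHKBP1 and LHX4 and at 7 of 9 and 9 of 9 of LPXN. With no filter on input signal, which adds dimmer probes, EIF3B was at -0.36 and SHKBP1 at -0.10. Without high-fertile bull 2 LHX4 was at 0.27 and OPCML at 0.24, and without subfertile bull 5 LPXN was at 0.22.

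Other gene regions with lower values in all 3 high-fertile bulls, none past the threshold, were CDH20 and EFNA5, a cadherin and an ephrin ligand (-0.53 and -0.47), TFPT and SAP18, subunits of chromatin complexes (-0.49 and -0.35), PSMC4, a proteasome ATPase (-0.44), BRD2, a bromodomain protein (-0.36), and C4H7orf23 (-0.49). Higher in all 3 were HCFC2, a host cell factor (0.35), RPL26, a ribosomal protein (0.29), LHX5, a LIM-homeodomain factor of the forebrain (0.22), and ESAM, an adhesion molecule of endothelium (0.12; -0.01 with no filter and the session block). MSX1, a homeobox gene of craniofacial development, and FBXL22, an F-box protein, were at 0.20 and 0.19, and with normexp correction at -0.04 and -0.02. At RPL26 immunoprecipitated DNA was well above background at 4 of 9 high-fertile and 7 of 9 subfertile spots.

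The sizes of these differences moved by over 1.5 times with the filter for 6 of these genes. With no filter CDH20 was at -0.11, PSMC4 at -0.16, C4H7orf23 at -0.30 and MSX1 at 0.02, and LHX5 and FBXL22 were at 0.37 and 0.34. Single bulls moved others as far: without high-fertile bull 2 C4H7orf23 was at -0.18 and BRD2 at -0.22, and without high-fertile bull 3 PSMC4 was at -0.21, TFPT at -0.30 and RPL26 at 0.19. EFNA5 was at -0.29 without high-fertile bull 5, SAP18 and MSX1 at -0.23 and 0.10 without subfertile bull 4, and HCFC2 at 0.22 without subfertile bull 5.

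Over the 737 gene regions limma called 0 (smallest adjusted p = 0.99986), while 6 had an unadjusted p below 0.05, all lower in high-fertile bulls and ABCF2, EIF3B, SHKBP1 and RPS18 among them. The groups did not overlap for 22 genes (2.99%; 9 higher, 13 lower). Chance gives 10% if all 6 arrays are exchangeable, but they parted by session, and the share chance gives for groups that cut across sessions was not computed. With the session as a block limma again called 0 genes, with 11 at an unadjusted p below 0.05, of which 4 were higher and 7 lower. The median difference over all genes was -0.08 without and -0.02 with the block. The median standard error was 0.25 without and 0.20 with the block, and the 95% confidence interval lay within 1 log2 unit of 0 for 597 genes (81.0%) without the block and for 704 (95.5%) with it. A test of whether the group difference itself differed between sessions called 0 genes with limma (25 at an unadjusted p below 0.05).

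**Figure D3:**
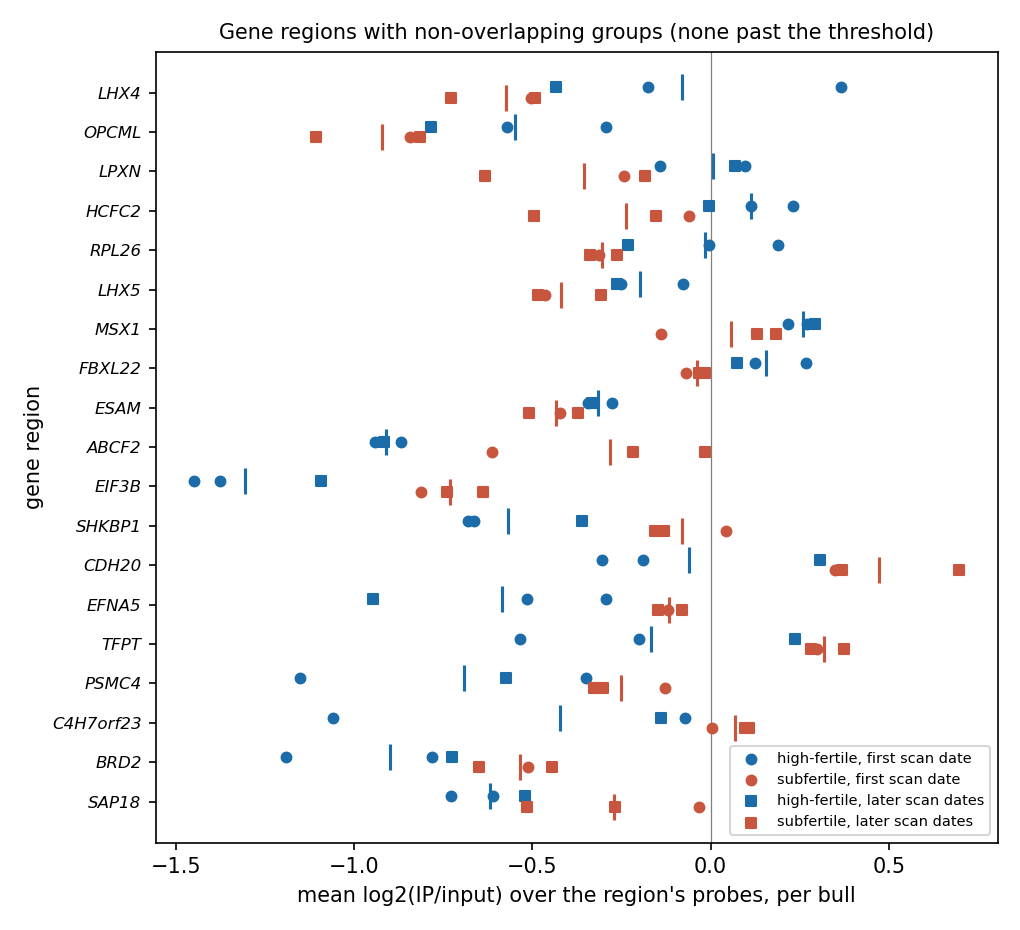
Mean log2(IP/input) of each bull (x axis, log2 units relative to the array's median) for the 19 named gene regions (y axis); blue points are high-fertile and red points subfertile bulls, circles the first scan date, squares later dates, and vertical ticks group means (n = 3 bulls each). The groups do not overlap in any of the 19 genes, which the naming rule requires, none passed the threshold, and ESAM, MSX1 and FBXL22 change sign in 1 or 2 other settings.

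Within the later dates alone, where 1 high-fertile bull stands against 2 subfertile bulls, limma called 4 gene regions. WDR4, a subunit of a tRNA methyltransferase, was higher in the high-fertile bull (1.19, SE 0.19; adjusted p = 0.00116), and ABCF2 (-0.80, SE 0.19) and EFNA5 (-0.83, SE 0.19) were lower, each with an adjusted p of 0.0475. On the first date WDR4 was at -0.16, ABCF2 at -0.29 and EFNA5 at -0.28, with an adjusted p of 0.999 for each. ABCF2 and EFNA5 were named because their groups do not overlap, which fixes their sign in both sessions, and WDR4 was named after its values were seen. These 4 calls rest on 1 residual degree of freedom and on the spread limma borrows from other genes. On the first date alone limma called 0 genes (14 at an unadjusted p below 0.05).

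Among single probes whose groups did not overlap, those with the smallest unadjusted p on the higher side lay in GLO1, a glyoxalase that clears methylglyoxal (1.53; chromosome 23, 13014896 to 13014955), and in KCNH1, a voltage-gated potassium channel (1.83; chromosome 16, 70098345 to 70098404). Immunoprecipitated DNA at the GLO1 probe was well above background in only 1 of 3 high-fertile and 1 of 3 subfertile bulls, and at the KCNH1 probe in 2 of 3 and 1 of 3. Both differences therefore rest largely on dim spots and their sizes are not exact. With normexp background correction they were 0.52 and 0.50, but its added offset of 50 by itself shrinks log ratios of dim spots. Probes without a gene name at 84434431 on chromosome 12 (1.71), 78896409 on chromosome 4 (1.74) and 16928911 on chromosome 3 (1.37) were also higher, and those at 25846672 on chromosome 28 (-1.94) and 58327034 on chromosome 24 (-1.40) lower; each was measured above background in 1 to 3 bulls of either group, and with normexp these 5 lay between 0.38 and 0.70 or at -0.44 and -0.31. At 3 further unnamed probes the immunoprecipitated signal was not well above background in any high-fertile bull. There the mean of the subfertile bulls was at least 1.39-fold (3840649 on chromosome 24) and 1.61-fold (27334094 on chromosome 19) above that of the high-fertile bulls. At 36297872 on chromosome 15 no fold above 1 was left. Each bound sets the dim spots at the lowest signal well above background on their array, and dyes were not swapped. The bounds hold for the group means on these arrays, not for each bull, and carry no interval. No probe passed: limma called 0 of 110686 (smallest adjusted p = 0.99998; 2036, or 1.84%, at an unadjusted p below 0.05), and the groups did not overlap for 6403 probes (5.78%; chance gives 10% only for exchangeable arrays). With the session as a block it called 0 (3855 at an unadjusted p below 0.05), on the first date alone 0 (4367), and on the later dates alone 34, of which 27 were higher in the high-fertile bull, 1 had a gene name and 8 had the same sign on the first date.

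Runs of neighbouring probes gave 0 calls by limma among 9463 (44 at an unadjusted p below 0.05; 208 with the session as a block). A run takes a gene name borne by at least 1 of its probes, and its other probes may have no name. On the lower side, a run of 8 overlapping probes held the name YTHDC2, an RNA helicase that germ cells need for meiosis (-0.67, SE 0.22, chromosome 10, 1888717 to 1888798). A run of 4 overlapping probes held the name MRAS, a Ras-family GTPase (-0.75, SE 0.25, chromosome 1, 132809402 to 132809473). With the session as a block these differences were -0.59 and -0.61. Of the runs whose groups did not overlap, the one with the smallest unadjusted p on the higher side had no gene name (0.93, SE 0.25; chromosome 22, 61645779 to 61645863).

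Developmental regulators, the homeobox, paired-box, GATA, T-box and related transcription factors, were the only list with 5 or more measured genes: 41 of its genes were tested. Their median difference was 0.03 against -0.08 over all genes, and 29 of the 41 were above 0 and 12 below. The sign relative to all genes turned with no filter (-0.18) and on the later dates alone (-0.05). With no filter and the session as a block it did not turn (0.03 against -0.001 over all genes). The members with the smallest unadjusted p were NKX2-2 (0.40), HOXC5 (0.28), FOXC2 (-0.38) and EOMES (0.27), regulators of the ventral neural tube, axial patterning, mesenchyme and mesoderm, and none was past the threshold. On the later dates alone NKX2-2 was at -0.21, HOXC5 at 0.03, FOXC2 at 0.09 and EOMES at 0.12. Leaving out 1 bull put NKX2-2 between 0.08 (without high-fertile bull 3) and 0.67 (without high-fertile bull 5), and FOXC2 between -0.21 (without high-fertile bull 2) and -0.68 (without high-fertile bull 5). EOMES lay between 0.14 (without subfertile bull 5) and 0.45 (without subfertile bull 1), and HOXC5 was at 0.13 without high-fertile bull 3. With no filter FOXC2 was at -0.11. Camera placed the list above other genes (p = 0.000702), but with an estimated correlation of 0.21 between its genes the p was 0.255. The rotation test fry of limma gave 0.603 as the p of a joint shift of the list's genes and 0.850 as that of changes in either direction. Over all genes 0 members passed, and adjusted over the list alone 0 passed.

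With the session as a block the developmental regulators lay 0.10 above all genes (camera p = 0.00185; 0.351 with an estimated correlation). They lay 0.28 above all genes on the first date (camera p = 2.07e-05; 0.240 with an estimated correlation) and -0.05 on the later dates (p = 0.0758; 0.734 with an estimated correlation). Camera on the interaction of group and session gave p = 6.06e-06, and 0.252 with an estimated correlation. Without subfertile bull 4, the only subfertile bull of the first date, the camera p was 0.131.

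The other lists kept at most 4 measured genes each and could not be tested as lists. Imprinted genes measured were PEG10, SGCE and IGF2R with a maternal mark and RASGRF1 and RTL1 with a paternal mark. Germline and sperm lists kept HSPA2, GFRA1, KDM3A and DNAH2, and the lists of bull fertility proteins and capacitation kept PRDX5, CCT5, ADCY9, ITPR1 and GNAI2. Pluripotency kept PRDM14, TFAP2C and MYC, epigenetic enzymes KDM3A, BMI1, SETD1A and EHMT1, stress genes HSPB3, HSPB6, HSPH1 and DNAJB6, and hormones INHBA and BMP4. RUNX3 remained of the leukocyte markers, ESRP1 and DSP of the epithelial markers, and no olfactory receptor remained. Over all genes none of these members passed. Adjusted over the list alone only the ribosomal protein gene RPS18 passed, as the only measured housekeeping gene and so without any adjustment. Its difference was -0.61 (SE 0.26; unadjusted p from limma 0.0460), with -1.05 on the first date and -0.03 on the later dates.

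Without the filter on input signal 13 lists could be tested, and camera called 0 of them (smallest adjusted p = 0.682; 0 at an unadjusted p below 0.05). The median difference over all 2779 genes was then 0.26 (-0.001 with the session as a block) and has to be set against that of each list. List medians were 0.50 for housekeeping genes, 0.49 for reproductive hormones, 0.46 for sperm structure and function, 0.43 for bull fertility proteins, 0.34 for epigenetic enzymes and 0.32 for capacitation signalling. They were 0.24 for stress genes, 0.20 for leukocyte markers, 0.17 for epithelial markers, 0.14 for genes with a maternal imprinting mark, 0.13 for germline genes, 0.08 for developmental regulators and 0.05 for pluripotency genes. For the housekeeping and stress lists camera's direction was opposite to that of the median. With the session as a block list medians lay between -0.10 (pluripotency) and 0.17 (bull fertility proteins), and again 0 lists passed (smallest adjusted p = 0.759). Sperm chromatin, genes with a paternal imprinting mark and olfactory receptors stayed below 5 genes.

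Within sperm, across both groups, the developmental regulators had a median log2(IP/input) -0.05 ± 0.12 (SD, 6 bulls) from that of all gene regions, below it in 4 of 6 bulls (exact sign-flip permutation p = 0.375). Their highest members were GATA2 and MSX1, with means of 0.30 ± 0.29 and 0.16 ± 0.16, and their lowest OLIG1 and HOXC4, with -0.73 ± 0.35 and -0.53 ± 0.38; OLIG1 was at -1.01, -1.19 and -0.94 on the first date and at -0.42, -0.38 and -0.46 on the later dates. Without the filter the developmental regulators lay at -0.34 ± 0.30 and the stress genes at -0.22 ± 0.13, below all genes in 6 of 6 bulls (exact sign-flip permutation p = 0.0312, the smallest possible; adjusted p = 0.203 over 13 lists). Both were further below on the first date: the developmental regulators lay at -0.57, -0.56 and -0.68 in high-fertile bulls 2 and 3 and subfertile bull 4, but at -0.04, 0.00 and -0.18 in high-fertile bull 5 and subfertile bulls 1 and 5. The stress genes lay at -0.41, -0.17 and -0.35 on the first date and at -0.13, -0.12 and -0.13 on the later dates. Genes of sperm structure and function lay at 0.21 ± 0.27 and genes with a maternal imprinting mark at 0.16 ± 0.25, each above all genes in 5 of 6 bulls. Pluripotency genes lay at -0.21 ± 0.21 and bull fertility proteins at -0.14 ± 0.20, each below all genes in 5 of 6 bulls. For pluripotency genes the values were -0.36, -0.47 and -0.35 on the first date and -0.02, -0.09 and 0.02 on the later dates. For sperm structure and function the values were 0.43, 0.53 and 0.29 on the first date and 0.15, 0.05 and -0.20 on the later dates. The adjusted p of the 11 other lists was 0.305 to 0.750.

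The spread of log2(IP/input) across each array was 0.66 ± 0.04 (SD over 3 bulls) in high-fertile and 0.57 ± 0.09 in subfertile bulls as a standard deviation (exact permutation p = 0.2), and 0.80 ± 0.02 against 0.71 ± 0.11 as an interquartile range (exact permutation p = 0.2). Probes at least 1 log2 unit above the array's median made up 5.40% ± 0.98 in high-fertile and 3.98% ± 1.57 in subfertile bulls (exact permutation p = 0.3). The smallest p this design allows is 0.1. Subfertile bull 1, whose header names another protocol, had the lowest standard deviation (0.47). Without it the group differences fell from 0.10 to 0.05 for the standard deviation, from 0.09 to 0.03 for the interquartile range and from 1.42 to 0.54 percentage points for the share. The share was 5.69% and 6.2% in high-fertile against 4.51% in the subfertile bull of the first date, and 4.30% in the high-fertile against 2.21% and 5.21% in subfertile bulls of the later dates.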

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

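The check for a bull far from the others was planned, and it was made on 18 values, of which 1 stood out, about as many as chance gives at 1 in 20. Without the filter on input signal, the 10 measured bull fertility proteins lay 0.22 log2 units above all gene regions in high-fertile bull 3, while the other 5 bulls lay between -0.32 and -0.12.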

How the results depend on the processing

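Settings fixed beforehand and those chosen after the data were seen (the session and scan date fits, centring over tested probes, runs, and no filter with the session block) are given together. Limma called 0 probes in 23 of 24 alternatives and 0 gene regions in 27 of 28; with only the later scan dates it called 34 probes and 4 gene regions, against 0 and 0, and the cause was not tested. Leaving out each bull in turn gave 0 probes and 0 genes every time. Probes at an unadjusted p below 0.05 numbered 445 (both channels above background) to 14803 (array weights), and gene regions 0 to 166 (array weights, smallest adjusted p = 0.0659). Without high-fertile bull 5 these counts were 12593 and 89, against 2036 and 6 with all bulls. It is the only high-fertile bull of the later dates, so without it the groups come close to the split by session. That split had 37249 probes and 307 genes at an unadjusted p below 0.05. The rise therefore cannot be told apart from the session.

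The list call for developmental regulators stood in 17 of 23 alternatives (adjusted p of the list over alternatives, 1.11e-05 to 0.904). It was lost, leaving 0 lists, with camera's estimated correlation (p = 0.255), normexp (0.111), no filter (adjusted p = 0.682), only the later scan dates (0.0758), and no filter with the session block (smallest adjusted p = 0.759); leaving out a bull gave 0 to 1 lists, with 0 only without subfertile bull 4 (0.131). The list relative to all genes reversed with no filter (-0.18) and on the later dates (-0.049). Over the 24 named genes, 599 values kept their sign and side of the threshold and 6 reversed: MSX1 (-0.036) and FBXL22 (-0.015) with normexp, FBXL22 with the median over probes (-0.033), ESAM with no filter and the session block (-0.0088), and FOXC2 (0.087) and NKX2-2 (-0.21) on the later dates; ABCF2 and EFNA5 passed on the later dates (adjusted p = 0.0475, over alternatives 0.0475 to 0.99986). Sizes moved more than signs: 20 of the 24 shrank by over 1.5 times with normexp, 7 with no filter and 15 on the later dates. Normexp was run with an added offset of 50, and an added offset by itself shrinks log ratios, most at dim spots. Median background-subtracted IP signals were only 10.8 (high-fertile bull 2) to 87.8 (subfertile bull 1). Shrinkage with normexp therefore does not by itself mark a difference as unstable, and the offset's part in it was not tested. The cause of the changes with no filter and on the later dates was not tested either. The 230 values of the 10 named probes kept sign and side, but all 10 shrank by over 1.5 times with normexp (0.38 to 0.70 higher, -0.21 to -0.44 lower) and 5 did on the later dates. At the lower probes without immunoprecipitated signal well above background in any high-fertile bull, these sizes are not exact. That holds for the probe at 36297872 on chromosome 15 (-0.21 with normexp), where no fold above 1 was left. For genes and probes named because their groups do not overlap, leaving out bulls cannot turn the sign. The share of probes 1 log2 unit above the median reversed with normexp (-0.26 percentage points); the other spread and enrichment values did not change sign or side.

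No paired analysis was possible because the groups share only the bull number 5. The feature class comparison and its alternatives were not run because the files name no classes. With both channels above background 21 of the 24 named genes had fewer than 3 probes left and gave no value (MSX1, FBXL22 and NKX2-2 did), and with a minimum of 5 probes 20 gave none, so these settings say nothing about those genes. Immunoprecipitated signal over background limits the arrays of the first date most: it was 37.6% to 58.6% of probes there and 76.5% to 85.2% on the later dates.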

Other observations

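Planned here were the splits of the bulls for the gene list and, written before their results were seen, the tests of probe GC content and of the filter on dim probes; the other tests, and the genes named in this part apart from EIF3B, were chosen after values had been seen. Relative to the median gene region of each array, EIF3B and SNX20, a sorting nexin, were at least 0.5 log2 units lower in all 6 bulls, and 0 genes were that much higher in all 6. If the sessions were independent, 0.423 genes would be low in both and 1.46 high in both. Within the later dates, 43 genes were at least 0.5 higher in all 3 bulls, among them FSCN1, an actin-bundling protein (mean 1.72; 0.39 on the first date), and VPS37B, of the endosomal sorting machinery (1.09; 0.46 on the first date). On those dates 24 genes were at least 0.5 lower in all 3 bulls, among them SNX11, another sorting nexin (-1.29; -0.17 on the first date), and VCL, the cytoskeletal linker vinculin (-0.94; 1.29 on the first date).

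The imprinted neighbours SGCE and PEG10 on chromosome 4 (12306375 to 12310429 and 12313019 to 12314538) carry a maternal methylation mark in mammals. SGCE had a mean log2(IP/input) of -0.74 ± 0.17 (SD) and was below the array median in 6 of 6 bulls. PEG10 was at -0.39, -0.21 and -0.23 on the first date (high-fertile 2 and 3, subfertile 4) and at 0.38, 0.27 and 0.27 on the later dates (high-fertile 5, subfertile 1 and 5). These values are relative to the array's median over all probes, not to the median gene region. On that scale the tested probes had medians of -0.33, -0.26 and -0.26 in the same bulls of the first date. On the later dates these medians were -0.01, -0.02 and -0.10. PEG10 thus lay close to the tested probes on the first date and above them on the later dates. The 47 tested probes of the X chromosome lay at 0.53, 0.68 and 0.51 relative to other chromosomes on the first date (high-fertile 2 and 3, subfertile 4) and at -0.26, -0.02 and -0.10 on the later dates (high-fertile 5, subfertile 1 and 5; exact sign-flip permutation p = 0.25 over the 6 bulls).

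The grouping of the arrays by scan session was weighed against 3 technical explanations and the fertility group. The slide is argued against by subfertile bull 1, which shared its slide with the first session's bulls but was scanned later and correlated better with the other slide by 0.777. Spot noise would cap the correlation between sessions, but corrected for duplicate spots the highest was 0.473. The corrected values were 0.878 to 0.911 within the later dates and 0.722 to 0.801 within the first date. Duplicate spots share any floor under dim signals, so this correction does not address such a floor. Removing a probe GC trend left a gap of 0.545 between correlations within and between sessions (0.620 before). Pairs of the same fertility group correlated less well than other pairs by a difference of -0.105. That difference was not matched for session and so partly restates the session layout. Same-group pairs from different sessions correlated at 0.151 at most, and different-group pairs from the same session at 0.442 at least. Median background-subtracted IP signals were 10.8, 26.4 and 15.3 in high-fertile bulls 2 and 3 and subfertile bull 4. They were 42.2, 87.8 and 63.2 in high-fertile bull 5 and subfertile bulls 1 and 5. This dimmer signal of the first date, scan date itself and the labelling or immunoprecipitation done with it remain open. So do unrecorded differences between the bulls, and these were not tested apart.

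The median difference of developmental regulators was 0.03, against -0.08 over all genes. The small camera p of the list may come from the correlation between its genes, since it was 0.255 with an estimated correlation. The list's place above all genes may come from 1 session, since it lay at -0.0489 relative to them on the later dates. Of the 10 splits of the 6 bulls, 3 gave as small a camera p (0.000702 for the real one, 1.66e-06 for the smallest other), and 10 splits are too few for a share under 0.05. Fertility remains among the open explanations, untested apart from these.

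Probes with 7 or more CpGs lay below probes with 0 or 1 by a difference of -0.30 ± 0.16 (SD) in log2(IP/input), in 6 of 6 bulls (exact sign-flip permutation p = 0.0312, the smallest possible). It was -0.37, -0.49 and -0.44 on the first date and -0.18, -0.09 and -0.22 on the later dates. On the later dates the fall was not steady over the CpG classes. Probes with 0 CpGs lay at -0.08, -0.07 and -0.06 from the tested probes' median in high-fertile bull 5 and subfertile bulls 1 and 5. The highest class there had 2 CpGs (0.05, 0.02 and 0.05). At fixed GC content the difference between probes with 7 or more CpGs and those with 0 or 1 was -0.284 (-0.44 to -0.10 over the bulls), which argues against base composition as the whole cause. Without the filter on dim probes it was -0.523, with -0.93, -0.91 and -0.80 on the first date but -0.16, -0.047 and -0.29 on the later dates. Subfertile bull 1 (-0.047) was just short of the bound of -0.05 set beforehand, so the filter cannot be told apart from other sources there. Low methylation of CpG-dense DNA in sperm is a candidate explanation that was not tested, since the design names no group for it.

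The comparison of the fertility groups called 0 probes and 0 genes, a number that no split can fall below, and the 10 splits of the bulls are too few for a share under 0.05. The highest other split called 16789 probes and 181 genes with the split as the only term. It is the split by scan session and points to that structure of the samples; with the fertility group as a second term the session called 8941 probes and 153 genes.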
